A study of Mus musculus with 18 samples.

How the data were processed

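The counts values are raw read counts per gene as deposited by the authors, 1 table of 30530 genes by 18 libraries, and all 18 columns were used. Per the submitters' processing notes, reads of polyadenylated, stranded libraries were checked with FastQC 0.11.9, aligned to the mouse genome GRCm38 (mm10) with GSNAP 2018-07-04 and counted over genes with featureCounts of Subread 1.5.2, and edgeR 3.26.8 was used afterwards. The strand setting, the handling of reads that align in several places and the annotation release are not given in the sources used here, so values of antisense genes and of near-identical paralogs are uncertain. Gene positions came from GENCODE M21, in which 30118 of the 30530 identifiers were found and 412 were not, and 12692 of the 12741 tested. Some symbols in the file are older ones, such as Emr1 for Adgre1 and Irg1 for Acod1. Raw reads were not analysed here.

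The tests, the 27 lists, the 9 comparisons and the first set of other settings were fixed from the sample labels before the data were examined. Counts were tested with edgeR 4.0.16 (limma 3.58.1, DESeq2 1.42.0, R 4.3.3; tables and figures with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9). Genes were kept by filterByExpr over the 6 groups, scaled with TMM factors and fitted with a mean per group in 1 model of all 18 libraries. Each comparison used the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the 12741 tested genes, and a gene was counted as changed at an adjusted p below 0.05. The common dispersion was 0.0370, a biological coefficient of variation of 0.192, with 12 residual degrees of freedom. Standard errors were taken as the absolute log2 fold change divided by the square root of F. CPM used library totals multiplied by the TMM factors, and principal components used log2 CPM with a prior count of 2.

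The 9 comparisons were 25HC against untreated B6 at rest and with PAM3, PAM3 against rest in untreated B6, in 25HC-treated B6 and in Ch25h-/-, Ch25h-/- against B6 at rest and with PAM3, and the interactions of PAM3 with 25HC and with genotype. Lists were tested with limma's camera on voom values at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 27 lists of a comparison. Of 486 list members 480 were in the file, 4 of them matched by identifier only. The lists covered cholesterol synthesis, sterol-responsive uptake, LXR targets, fatty acid synthesis, lipid droplets, oxysterol metabolism, type I interferon-stimulated genes, inflammatory mediators, NF-kB, AP-1, ATF4, endoplasmic reticulum chaperones, NRF2, cell cycle, glycolysis and hypoxia, mitochondrial respiration, alternative activation, macrophage identity, antigen presentation and markers of osteoclasts and 7 other cell types. Genes chosen in 1 comparison were followed into another with camera and fry, and the size of a PAM3 response was the median interaction over genes chosen in libraries outside that interaction, signed by direction and tested with fry.

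Named genes followed a fixed rule. For each comparison except the PAM3 responses of 25HC-treated B6 and of Ch25h-/- it took the 8 largest rises and 8 largest falls with an adjusted p below 0.05, a mean of at least 5 CPM in a compared group and, between 2 groups, no overlap of their libraries. Predicted genes, pseudogenes and features without a symbol were left out. A few genes that met the rule are not reported here. Up to 4 members of each list with the smallest adjusted p were added, with up to 2 members of highest CPM for lists without a call and for other cell types, and Ch25h, Tlr1, Tlr2 and Tlr6 whatever their values. The text names a part of these, chosen for calls that held without any 1 library where such genes existed. For genes with 0 counts in a group the fold change is a lower bound against 3 counts over the group, and for 1 to 3 counts the ratio is given with a 95% interval for counting error.

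The mouse number was checked as a pairing by correlating deviations from group means across genes. Within B6 at rest, untreated and 25HC-treated libraries of the same number correlated with r = 0.448, 0.581 and 0.348, and with PAM3 with r = 0.406, 0.377 and -0.162. Across genotypes r was 0.574, 0.705 and 0.327 at rest and 0.322, 0.459 and 0.0949 with PAM3. The number was used as a block within a genotype and across genotypes, both at rest and with PAM3, although with PAM3 the pairing across genotypes was not clear. Replicate libraries were checked for duplicates and none were found.

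The other settings fixed in advance were DESeq2 size factors in edgeR, the DESeq2 Wald test, no filter, a filter at 1 CPM, only the groups compared in the fit, each library left out in turn, the animal or number as block, a limma-voom fit with the animal as random effect (estimated correlation 0.168), removal of genes within 10 Mb of Ch25h, windows of 5 and 20 Mb, an estimated inter-gene correlation, fry, removal of Ifit genes from the interferon list and sets changed at least 2-fold. Added after the data were seen were scaling by library size alone, thinning of every library to 14040513 counts, removal of replicate 2 from every group and an estimated correlation in the blocked fit. The code was tested on simulated data in which 200 genes were changed in counts drawn with the fitted levels, depths and dispersions of the real libraries. Of simulated 2-fold changes 68.7% were recovered for 25HC at rest, 57.6% for genotype with PAM3 and 34.8% and 32.8% for the 2 interactions, and 3.25 to 7.69% of calls were false. For the neutrophil list at rest each library was also left out with an estimated correlation, a setting added after the data were seen. Real groups were also compared with other splits of the same libraries. For comparisons of 2 groups these were all 10 splits, and for each interaction 100, the real one and others drawn at random.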

Results

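Gene expression was measured by RNA-seq of polyadenylated RNA in bone-marrow-derived macrophages, phagocytes grown in culture from mouse bone marrow. The variable of the study was 25-hydroxycholesterol (25HC), an oxysterol that macrophages make from cholesterol with the enzyme encoded by Ch25h. Cells of C57BL/6 mice (B6) received no oxysterol or 5 µM of 25HC for 18 hours, and each of these was studied at rest or after 300 ng/mL of Pam3CSK4 (PAM3), a synthetic bacterial lipopeptide sensed by Toll-like receptors 1 and 2. Cells of Ch25h-/- mice, which received no 25HC, were studied at rest and with PAM3. The 6 groups held 3 libraries each, numbered 1 to 3 by mouse, 18 libraries in all. The labels give a stimulation time, without a unit, of 18 for the PAM3 libraries and 0 for those at rest. Whether cells at rest were cultured for as long is not given in the labels. Comparisons of PAM3 with rest, and the interactions built on them, may therefore also include a difference in time.

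Total gene counts ran from 14.04 M to 150.4 M counts per library, a 10.7-fold range. Medians per group were 44.9 M in untreated B6 at rest, 24.2 M after 25HC at rest, 42.1 M in B6 with PAM3 and 59.8 M with 25HC and PAM3. In Ch25h-/- cells they were 15.8 M at rest and 23.1 M with PAM3. Levels are given below as CPM on scaled library sizes, as mean ± SD with n = 3 in each group. Unless a block is named, edgeR p-values rest on the spread among libraries within the 6 groups, with the pairing by mouse left out. The first principal component, with 62.9% of the variance, separated PAM3 from rest, and the second, with 17.9%, separated 25HC-treated from untreated cells. The third, with 7.93%, set replicate 2 at rest apart, at 31.3 in B6 and 75.6 in Ch25h-/-, where the other libraries of those groups lay between -18.9 and 9.97. Mitochondrially encoded mRNA made up 1.11 to 2.13% of counts and was highest in the 3 Ch25h-/- libraries at rest (2.05, 2.13 and 2.09%, against 1.59, 1.33 and 1.79% in untreated B6 at rest).

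**Figure D1:**
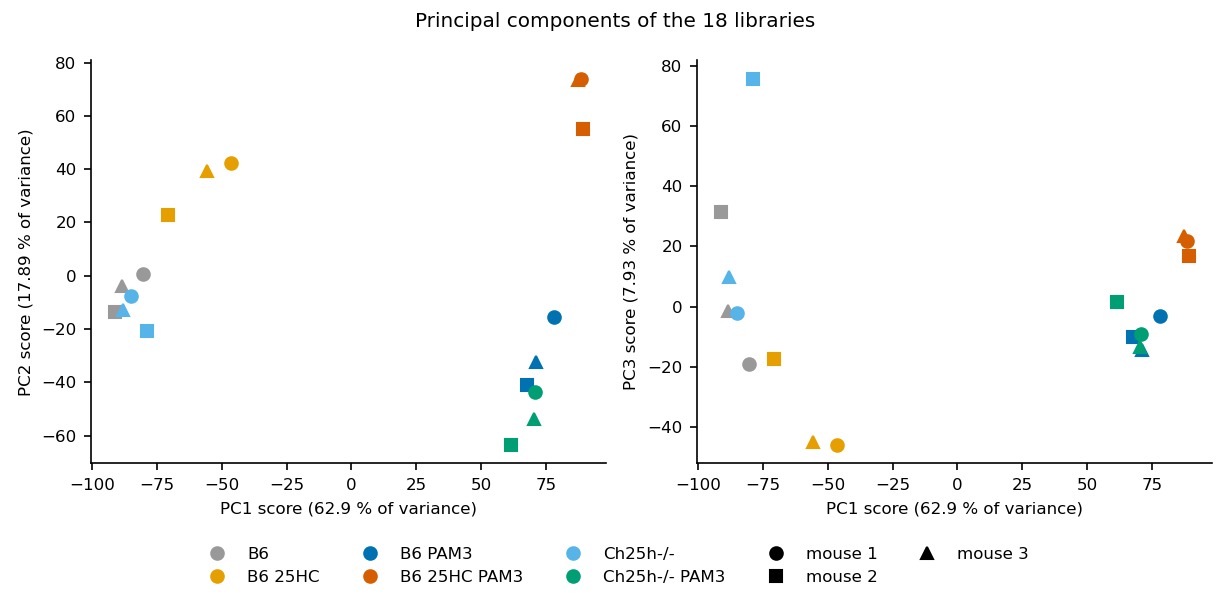
Scores of the 18 libraries on principal components of log2 CPM, component 1 against 2 and 1 against 3, with each point a library coloured by group and numbered by mouse. PAM3 separates along component 1 (62.9% of the variance), 25HC along component 2 (17.9%), and replicate 2 at rest lies apart on component 3 (7.93%).

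The targeted gene was examined first. Ch25h (GRCm38 chromosome 19, 34473778 to 34475164, minus strand), which encodes cholesterol 25-hydroxylase, was present in every B6 library and close to absent in every Ch25h-/- library. In untreated B6 at rest it lay at 20.4, 3.16 and 10.2 CPM in replicates 1, 2 and 3, and after 25HC at 40.8, 16.3 and 25.8 CPM. With PAM3 it lay at 3.55, 1.67 and 2.14 CPM in untreated B6 and at 4.92, 3.264 and 3.86 CPM after 25HC. Ch25h-/- cells held 2, 0 and 2 counts at rest (0.0990, 0 and 0.119 CPM) and 1, 2 and 0 counts with PAM3 (0.0477, 0.0871 and 0 CPM). With PAM3 the ratio of B6 to Ch25h-/- was 45.5-fold, with a 95% counting interval of 15.5 to 221. Such intervals, and the floor of 3 counts over a group used for genes at 0, cover counting error only. PAM3 lowered Ch25h in untreated B6 (log2 fold change -2.21 ± 0.53 SE, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00195) and after 25HC (-2.79 ± 0.53, edgeR adjusted p = 0.000345), in 3 of 3 animals each. The first value was -1.45 without replicate 1 of untreated B6 at rest. The higher Ch25h after 25HC was short of the threshold at rest (1.31 ± 0.50, edgeR adjusted p = 0.0653, past it at 0.00470 with the animal as block and at 0.00928 without untreated replicate 1 or 0.0371 without 25HC replicate 2) and with PAM3 (0.73 ± 0.52, edgeR adjusted p = 0.264).

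**Figure D2:**
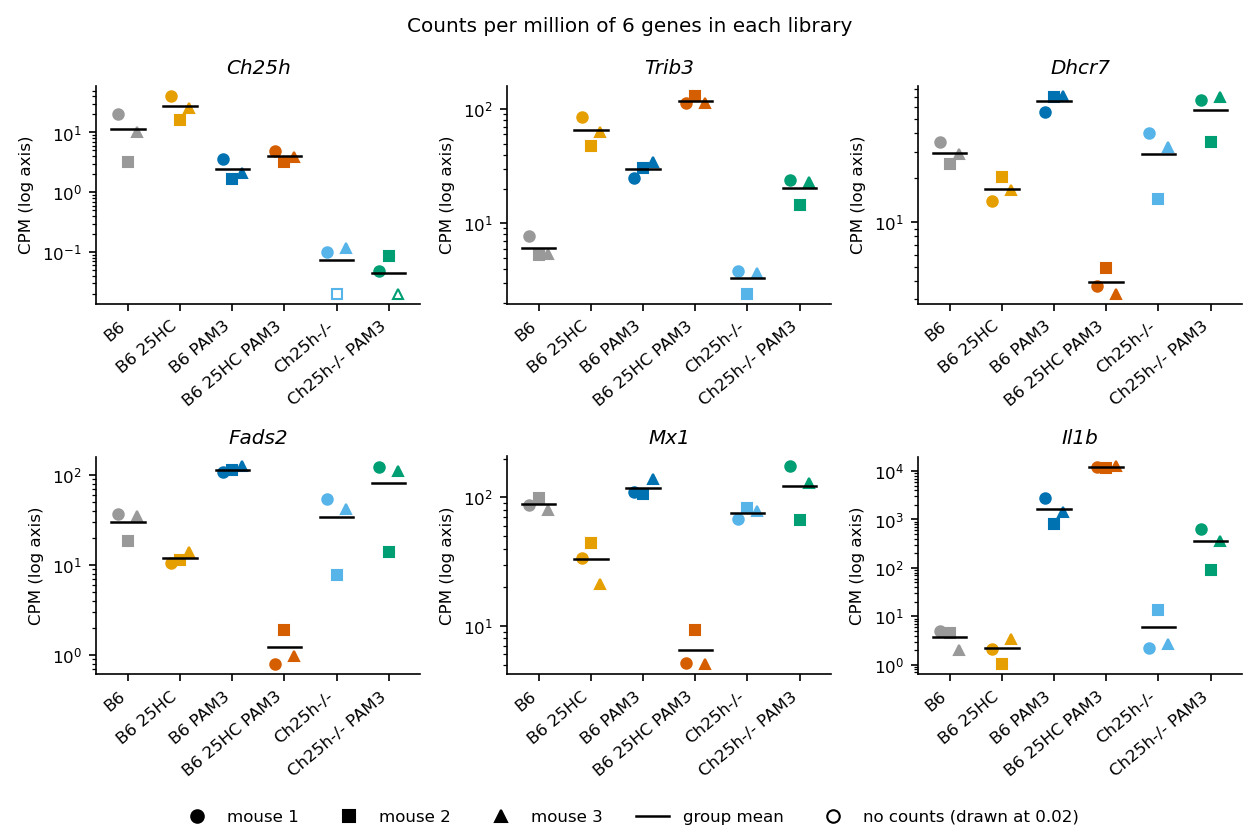
CPM on a log axis of Ch25h, Trib3, Dhcr7, Fads2, Mx1 and Il1b in each of the 18 libraries by group, points for libraries and lines for group means, with libraries at 0 counts drawn open at the bottom. Ch25h is near 0 in all 6 Ch25h-/- libraries, Fads2 falls from 115 to 1.22 CPM and Il1b rises from 1658 to 12146 CPM when 25HC precedes PAM3.

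The comparison of 25HC-treated with untreated B6 cells at rest asked what the oxysterol changes before any stimulus. Of genes of the integrated stress response governed by the transcription factor ATF4, 22 of 25 rose, while 17 of 45 interferon-stimulated and 7 of 20 cholesterol synthesis genes fell. None of the 3 lists was called as a list with an estimated correlation (camera adjusted p = 0.384, 0.656 and 0.656). Trib3 (chromosome 2, 152337422 to 152344032, minus strand), a stress-induced pseudokinase, rose from 6.12 ± 1.42 to 65.4 ± 19.2 CPM (log2 fold change 3.43 ± 0.25 SE, edgeR quasi-likelihood adjusted p = 2.5e-06). Mx1 (chromosome 16, 97447035 to 97462907, minus strand), an interferon-induced antiviral GTPase, fell from 89.0 ± 9.69 to 33.1 ± 11.5 CPM (-1.43 ± 0.32, edgeR adjusted p = 0.00502). Soat2, which esterifies cholesterol, rose from 0.812 ± 0.377 to 12.2 ± 3.67 CPM (3.97 ± 0.39, edgeR adjusted p = 2.1e-05). In all, 3334 of 12741 tested genes changed, 1886 higher and 1448 lower, and 494 and 445 of these by at least 2-fold. Each of the 81 named genes that passed moved the same way in all 3 animals, which here and below follows in large part from how named genes were chosen.

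Of the 25 tested ATF4 genes, 22 rose and 0 fell (22 and 0 adjusted over the list alone), with a median log2 fold change of 1.56 ± 1.07 (SD over members). This list passed limma's camera test at the preset correlation (adjusted p = 3.0e-14) and not with an estimated one (adjusted p = 0.384 with an estimated correlation). Atf4 itself rose from 106 ± 20.3 to 349 ± 60.4 CPM and Atf5, a related factor, from 26.8 ± 4.62 to 107 ± 15.2 CPM. In the AP-1 and ATF3 family 12 of 15 genes rose (12 adjusted over the list alone), with a median of 1.03 (camera adjusted p = 9.9e-05, adjusted p = 0.536 with an estimated correlation). Fos, an immediate-early factor, went from 22.9 ± 3.48 to 73.7 ± 30.4 CPM. The other lists called here shared an adjusted p = 0.656 with an estimated correlation. Among endoplasmic reticulum chaperones 8 of 20 rose (median 0.43, camera adjusted p = 9.9e-05), including Xbp1, from 141 ± 21.5 to 256 ± 15.4 CPM, and Hyou1, from 126 ± 43.3 to 306 ± 36.0 CPM. In the NF-kB list 9 of 25 rose (11 adjusted over the list alone, median 0.52, camera adjusted p = 9.9e-05), among them the phosphatase gene Dusp1, from 21.2 ± 4.59 to 86.7 ± 28.1 CPM. In the glycolysis and hypoxia list 9 of 23 rose (median 0.56, camera adjusted p = 0.000153), with the glucose transporter gene Slc2a1 at 1.90 ± 0.33 and the phosphofructokinase gene Pfkp at 1.86 ± 0.31. NRF2 antioxidant targets gave 6 rises of 16 (7 adjusted over the list alone, median 0.48, camera adjusted p = 0.0399).

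Cholesterol synthesis fell in 7 of 20 genes (14 adjusted over the list alone), with a median of -0.75 ± 0.49 (camera adjusted p = 0.00243, adjusted p = 0.656 with an estimated correlation). Tm7sf2, a sterol reductase, fell from 10.7 ± 1.25 to 4.93 ± 0.727 CPM, and Stard4, a sterol transfer protein under the same control, from 52.4 ± 23.7 to 15.2 ± 2.09 CPM. The list of sterol-responsive uptake genes had 3 of 9 lower and missed the threshold (median -0.57, camera adjusted p = 0.145). It passed, lower, without replicate 2 of every group (camera adjusted p = 0.00635). Abcg1, the cholesterol exporter induced by the oxysterol receptor LXR, rose from 319 ± 90.9 to 646 ± 46.2 CPM (1.02 ± 0.22, edgeR quasi-likelihood adjusted p = 0.00414). The LXR list as a whole, with 3 of 17 higher and 1 lower, did not pass (median 0.09, camera adjusted p = 0.583). Of 45 type I interferon-stimulated genes 17 fell and 0 rose (26 adjusted over the list alone), with a median of -0.69 ± 0.53 (camera adjusted p = 5.9e-07, adjusted p = 0.656 with an estimated correlation). Iigp1, an interferon-inducible GTPase, fell from 17.9 ± 1.18 to 3.06 ± 1.64 CPM. Antigen presentation genes had 2 of 18 lower (median -0.31, camera adjusted p = 0.0247, adjusted p = 0.656 with an estimated correlation).

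Surface receptors changed in both directions. Tlr1, which pairs with Tlr2 to bind PAM3, fell from 79.1 ± 5.38 to 32.3 ± 6.75 CPM (-1.29 ± 0.14, edgeR quasi-likelihood adjusted p = 3.5e-05), and Tlr6, the other partner, from 23.4 ± 2.13 to 13.3 ± 1.92 CPM (-0.81 ± 0.13). Tlr2 went from 151 ± 26.6 to 208 ± 61.6 CPM, short of the threshold (0.46 ± 0.20, edgeR adjusted p = 0.0941). Cd14, a co-receptor for bacterial lipids, rose from 787 ± 132 to 2023 ± 437 CPM, and Klf4, a transcription factor, from 23.2 ± 0.393 to 82.4 ± 19.9 CPM. The scavenger receptor genes Stab1 (-0.96 ± 0.16) and Cd163 (-1.95 ± 0.44) fell. The alternative activation list (1 of 17 higher, 4 lower, median 0.00, camera adjusted p = 0.646), macrophage identity (3 of 18 higher, 6 lower, median -0.40, camera adjusted p = 0.137), fatty acid synthesis (median -0.09, camera adjusted p = 0.873), oxysterol metabolism (median 0.12, camera adjusted p = 0.447) and mitochondrial respiration (median 0.11, camera adjusted p = 0.294) did not pass. The lipid droplet list had a median of 0.09 and the osteoclast list one of -0.31, each opposite in sign to its mean or test, and neither passed (camera adjusted p = 0.943 and 0.873).

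The count at rest fell to 1524 without 25HC replicate 1, 1612 without 25HC replicate 3 and 2097 without untreated replicate 3, and was 5103 without replicate 2 of every group. NRF2 missed the threshold without untreated replicate 2 (camera adjusted p = 0.0768) or 25HC replicate 1 (0.125) or 3 (0.0522), and antigen presentation without untreated replicate 2 (0.166) or 25HC replicate 3 (0.0743). Inflammatory mediators (5 of 31 higher, 1 lower, median 0.81, camera adjusted p = 0.0987) passed without untreated replicate 1 (0.0391) or 25HC replicate 2 (0.0486) and, with the animal as block, at 0.00632. Cell cycle genes (median -0.29, camera adjusted p = 0.282) passed without untreated replicate 2 (0.00452) and with the animal as block (0.0250).

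The same treatment was then compared in cells stimulated with PAM3, which asked how prior 25HC alters the stimulated state. All 20 cholesterol synthesis genes and 41 of 45 interferon-stimulated genes fell while 17 of 31 inflammatory mediators rose, lists that were not called with an estimated correlation (camera adjusted p = 0.553 each). Fads2 (chromosome 19, 10062765 to 10101746, minus strand), a fatty acid desaturase, fell from 115 ± 9.16 to 1.22 ± 0.595 CPM (-6.49 ± 0.81 SE, edgeR quasi-likelihood adjusted p = 2.0e-05). Mx1 fell from 118 ± 17.9 to 6.51 ± 2.44 CPM (-4.17 ± 0.36, edgeR adjusted p = 9.1e-07). Thbs1 (chromosome 2, 118111876 to 118127133, plus strand), which encodes the matrix glycoprotein thrombospondin 1, rose from 46.9 ± 26.1 to 2377 ± 756 CPM (5.67 ± 1.15, edgeR adjusted p = 0.000993). In all, 5750 genes changed, 2744 higher and 3006 lower, 906 and 1295 by at least 2-fold, and each of the 95 named genes that passed moved the same way in all 3 animals.

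All 20 cholesterol synthesis genes fell (20 adjusted over the list alone), with a median of -2.79 ± 1.04 (camera adjusted p = 3.0e-12). With an estimated correlation this list and the others called with PAM3 each had an adjusted p = 0.553 with an estimated correlation. Dhcr7, a sterol reductase late in the pathway, fell from 66.1 ± 8.71 to 3.95 ± 0.849 CPM (-4.05 ± 0.35, edgeR adjusted p = 1.1e-06). Of 9 sterol-responsive uptake genes 6 fell (median -1.94, camera adjusted p = 0.0213, and 0.0515 without B6 PAM3 replicate 1). Fatty acid synthesis had 12 of 15 lower (median -1.30, camera adjusted p = 9.0e-05). Scd1 (chromosome 19, 44394455 to 44407879, minus strand), a desaturase, fell from 227 ± 37.0 to 8.85 ± 1.39 CPM and Acly, which makes cytosolic acetyl-CoA, from 423 ± 2.83 to 157 ± 3.77 CPM. LXR targets split, with 4 of 17 higher and 9 lower (4 and 12 adjusted over the list alone). Abcg1 rose from 248 ± 16.5 to 652 ± 33.9 CPM while Nr1h3, which encodes LXR alpha, fell from 96.8 ± 10.9 to 31.1 ± 9.30 CPM. That list missed the threshold (median -1.31, camera adjusted p = 0.106) and passed with the animal as block (0.0101). Hilpda, a lipid droplet protein, rose from 4.81 ± 0.490 to 55.9 ± 8.18 CPM (3.54 ± 0.17, edgeR quasi-likelihood adjusted p = 9.9e-09).

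Of the 45 interferon-stimulated genes 41 fell and 0 rose (42 and 0 adjusted over the list alone), with a median of -1.95 ± 0.98 (camera adjusted p = 5.5e-16, adjusted p = 0.553 with an estimated correlation). Igtp, an interferon-inducible GTPase, fell from 87.8 ± 15.3 to 18.98 ± 2.93 CPM and Rtp4 from 190 ± 33.9 to 31.6 ± 9.63 CPM. Values of Ifit family members are uncertain, as the handling of reads shared by near-identical copies is not given in the sources used here. Of 31 inflammatory mediators 17 rose and 4 fell (19 and 4 adjusted over the list alone), with a median of 1.90 ± 2.36 (camera adjusted p = 0.000115, adjusted p = 0.553 with an estimated correlation). Csf1, the macrophage growth factor, rose from 7.36 ± 3.82 to 40.1 ± 3.78 CPM, whereas Il10, an anti-inflammatory cytokine, fell from 20.9 ± 5.64 to 5.08 ± 1.88 CPM. In the NF-kB list 13 of 25 rose and 3 fell (median 0.66, camera adjusted p = 0.00754). Tnfaip3, a feedback inhibitor, rose from 121 ± 33.7 to 420 ± 25.2 CPM and Tlr2 from 361 ± 56.9 to 902 ± 10.6 CPM (1.32 ± 0.20, edgeR quasi-likelihood adjusted p = 8.7e-05). Tlr1 fell from 499 ± 30.8 to 223 ± 31.4 CPM (-1.17 ± 0.13), and Tlr6 lay at 37.7 ± 3.79 and 36.4 ± 1.32 CPM (edgeR adjusted p = 0.792).

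The ATF4 and NRF2 lists also rose with PAM3 present. ATF4 genes rose in 9 of 25 (median 0.42, camera adjusted p = 0.00404). NRF2 targets rose in 11 of 16 and fell in 2 (median 0.99, camera adjusted p = 0.00754). Both lists had an adjusted p = 0.553 with an estimated correlation. Endoplasmic reticulum chaperones, called higher with 25HC at rest, ran lower here and did not pass (camera adjusted p = 0.424). Prdx1, a peroxide scavenger, went from 840 ± 291 to 3783 ± 798 CPM. Mitochondrial respiration fell in 17 of 29 genes (median -0.38, camera adjusted p = 0.000629, adjusted p = 0.553 with an estimated correlation), among them Cox5a, a subunit of cytochrome oxidase, from 221 ± 35.5 to 125 ± 20.4 CPM. The costimulatory ligand genes Cd80 and Cd86 rose, from 6.70 ± 1.56 to 55.7 ± 13.2 CPM and from 5.39 ± 2.71 to 61.7 ± 10.9 CPM, while antigen presentation as a list (3 of 18 higher, 10 lower, median -0.66) had a camera adjusted p = 0.0973 and passed with the animal as block (0.0397). Arg1, an enzyme of alternatively activated macrophages, rose from 0.983 ± 0.407 to 34.04 ± 17.6 CPM. The AP-1 list (8 of 15 higher, 3 lower, median 0.53, camera adjusted p = 0.0557) passed with the animal as block (0.0420) and without B6 PAM3 replicate 2 (0.0270) or 25HC PAM3 replicate 1 (0.0406) or 3 (0.0328). Cell cycle (0 of 30 higher, 7 lower, 4 adjusted over the list alone, median -0.90, camera adjusted p = 0.0973) passed with the block (0.00233).

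The effects of 25HC in resting and stimulated cells overlapped. Of the genes that rose at rest 787 also rose with PAM3, where 406 would be shared by independent lists, and of those that fell 671 also fell, where 342 would (Fisher's exact test, two-sided, p = 4.1e-104 and 1.9e-91). Across 12741 genes the log2 fold changes of both states correlated with Pearson's r = 0.432 and Spearman's rho = 0.343, and genes are not independent replicates. The genes that rose at rest had a median of 0.271 with PAM3, 72.3% of them above 0 (camera p = 1.1e-13, p = 0.140 with an estimated correlation). Those that fell had a median of -0.424, 71.1% of them below 0 (camera p = 1.7e-09, p = 0.160 with an estimated correlation).

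**Figure D3:**
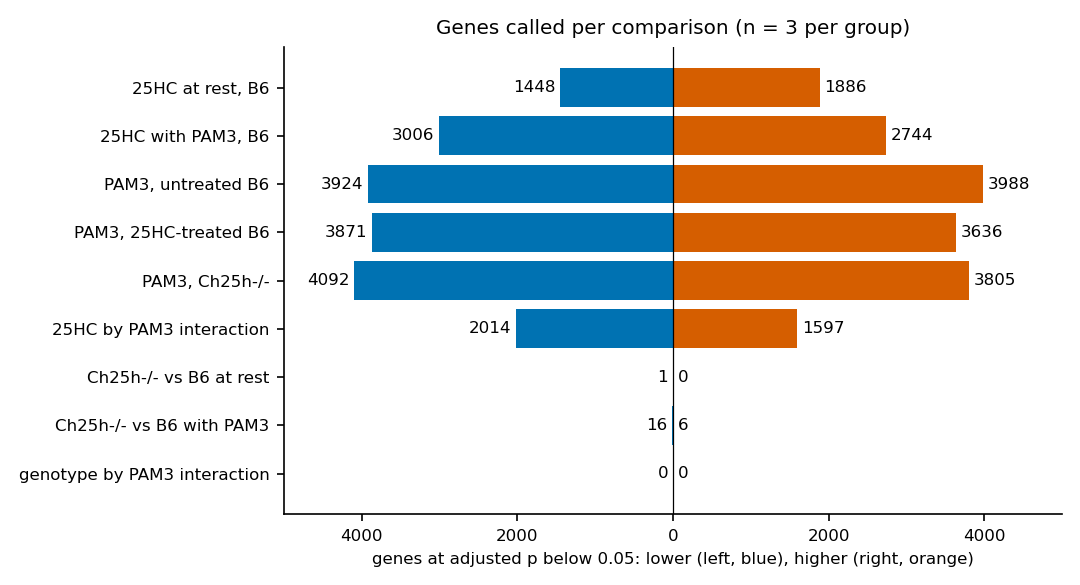
Number of genes with an edgeR Benjamini-Hochberg adjusted p below 0.05 in each of the 9 comparisons, bars above 0 for genes higher and below 0 for genes lower. The PAM3 responses change 7507 to 7912 genes, 25HC 3334 at rest and 5750 with PAM3, and loss of Ch25h 1 and 22.

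The response of untreated B6 cells to PAM3 gave the reference for the oxysterol. Some of the named genes rose by very large factors. Saa3 (chromosome 7, 46711998 to 46715700, minus strand), an acute-phase apolipoprotein, rose from 6.52 ± 4.03 to 33077 ± 7217 CPM (12.29 ± 0.83 SE, edgeR quasi-likelihood adjusted p = 2.1e-08). Marco (chromosome 1, 120474538 to 120505024, minus strand), a scavenger receptor, rose from 0.621 ± 0.309 to 1209.6 ± 168 CPM (10.83 ± 0.40, edgeR adjusted p = 6.0e-11). Il1b (chromosome 2, 129364570 to 129371139, minus strand), which encodes interleukin-1 beta, rose from 3.82 ± 1.56 to 1658 ± 999.9 CPM (8.76 ± 0.95, edgeR adjusted p = 1.9e-06). Mrc1 (chromosome 2, 14229392 to 14332057, plus strand), the mannose receptor, fell from 3015 ± 368 to 34.9 ± 8.56 CPM (-6.43 ± 0.59, edgeR adjusted p = 3.8e-07). In all, 7912 genes changed, 3988 higher and 3924 lower, and each of the 103 named genes that passed moved the same way in all 3 animals. With library size alone as scaling the median of all genes shifted by -0.203 and the calls became 2867 higher and 5053 lower.

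Of 31 inflammatory mediators 27 rose (28 adjusted over the list alone), with a median of 3.60 ± 3.17, or 3.54 with 5 members near 0 counts set at their bounds (camera adjusted p = 1.3e-06, adjusted p = 0.598 with an estimated correlation). In the NF-kB list 21 of 25 rose and 0 fell (median 1.89, camera adjusted p = 3.9e-08, adjusted p = 0.536 with an estimated correlation), with Sod2, the mitochondrial superoxide dismutase, going from 39.9 ± 5.77 to 1402 ± 109 CPM. Glycolysis and hypoxia genes rose in 21 of 23 (22 adjusted over the list alone, median 2.07, camera adjusted p = 3.9e-08, adjusted p = 0.536 with an estimated correlation). Hk2, a hexokinase, went from 27.4 ± 4.40 to 268 ± 3.38 CPM. Cholesterol synthesis rose in 19 of 20 genes (median 1.88, camera adjusted p = 2.6e-06) and fatty acid synthesis in 12 of 15, with 1 lower (median 1.70, camera adjusted p = 0.00288). For both lists adjusted p = 0.598 with an estimated correlation. Mvd, an enzyme of the mevalonate pathway, rose from 10.9 ± 1.01 to 96.7 ± 8.62 CPM. Endoplasmic reticulum chaperones (17 of 20, median 0.80, camera adjusted p = 0.000333) and mitochondrial respiration (20 of 29, median 0.45, camera adjusted p = 0.000244) rose, again with adjusted p = 0.598 with an estimated correlation. ATF4 genes rose in 23 of 25 (median 1.93, camera adjusted p = 5.4e-07, adjusted p = 0.536 with an estimated correlation).

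Cell cycle genes fell in 26 of 30 (27 adjusted over the list alone, median -3.33, camera adjusted p = 4.5e-07, adjusted p = 0.598 with an estimated correlation), with the mitotic cyclin gene Ccnb2 going from 35.2 ± 8.60 to 1.09 ± 0.210 CPM. Alternative activation genes had 11 of 17 lower and 4 higher (median -1.93, camera adjusted p = 0.0141, adjusted p = 0.294 with an estimated correlation). NRF2 targets (9 of 16 higher, 2 lower, median 0.55, camera adjusted p = 0.0312, adjusted p = 0.692 with an estimated correlation) missed the threshold without B6 PAM3 replicate 1 (0.0655) or 3 (0.0824). Interferon-stimulated genes (16 of 45 higher, 3 lower, median 0.41, camera adjusted p = 0.0698) passed without replicate 2 of B6 at rest (0.0384) or with PAM3 (0.0189) and with the animal as block (0.0318). Tlr1 rose from 79.1 ± 5.38 to 499 ± 30.8 CPM (2.66 ± 0.14), Tlr2 by a log2 fold change of 1.26 ± 0.20 and Tlr6 by 0.69 ± 0.13. The LXR and lipid droplet lists had medians of -0.36 and -0.15, each opposite in sign to its mean or test, and did not pass (camera adjusted p = 0.964 and 0.747). For genes at or near 0 counts in a group, Raver2 was at least 834-fold higher and Abca6 at least 622-fold lower with PAM3, and Nhs was 1823-fold higher, with a counting interval of 327 to 72028.

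After 25HC the PAM3 response was measured in the same way, to ask which parts of it the oxysterol altered. Il1b rose from 2.20 ± 1.22 to 12146 ± 382 CPM (12.42 ± 1.09 SE, edgeR quasi-likelihood adjusted p = 3.0e-07). Il6, another pyrogenic cytokine, rose from 0.0711 ± 0.0304 to 633 ± 64.6 CPM (13.04 ± 1.19, edgeR adjusted p = 4.3e-07). Cd274, which encodes the checkpoint ligand PD-L1, rose from 16.1 ± 2.11 to 954 ± 84.0 CPM. Mx1 fell by 2.33 ± 0.33 on the log2 scale and Dhcr7 by 2.08 ± 0.33. In all, 7507 genes changed, 3636 higher and 3871 lower, and each of the 88 named genes that passed moved the same way in all 3 animals. With library size alone the median shifted by -0.184 and the calls became 2501 higher and 4915 lower.

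Inflammatory mediators rose in 29 of 31 genes (median 5.14, camera adjusted p = 1.0e-09) and NF-kB genes in 21 of 25 (21 higher and 1 lower adjusted over the list alone, median 1.79, camera adjusted p = 1.8e-09), both with adjusted p = 0.662 with an estimated correlation. The growth factor gene Csf2 was at least 503-fold higher, and Csf3 was 1256-fold higher with a counting interval of 225 to 49631. The other called lists had an adjusted p = 0.751 with an estimated correlation. Interferon-stimulated genes fell in 28 of 45, with 4 higher (29 and 4 adjusted over the list alone, median -0.82, camera adjusted p = 0.00269). Cell cycle genes fell in 29 of 30 (median -4.02, camera adjusted p = 1.0e-08). Glycolysis rose in 19 of 23 (median 1.22, camera adjusted p = 6.9e-06), NRF2 targets in 12 of 16 with 1 lower (median 1.39, camera adjusted p = 0.000373) and ATF4 genes in 13 of 25 with 1 lower (median 0.81, camera adjusted p = 0.0114). Cholesterol synthesis had 3 of 20 higher and 5 lower and did not pass (median -0.08, camera adjusted p = 0.901), nor did fatty acid synthesis (4 higher and 4 lower of 15, median -0.25, camera adjusted p = 0.901). Mitochondrial respiration had 7 of 29 higher and 4 lower, with a median of 0.00 opposite in sign to its test (camera adjusted p = 0.702).

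**Figure D4:**
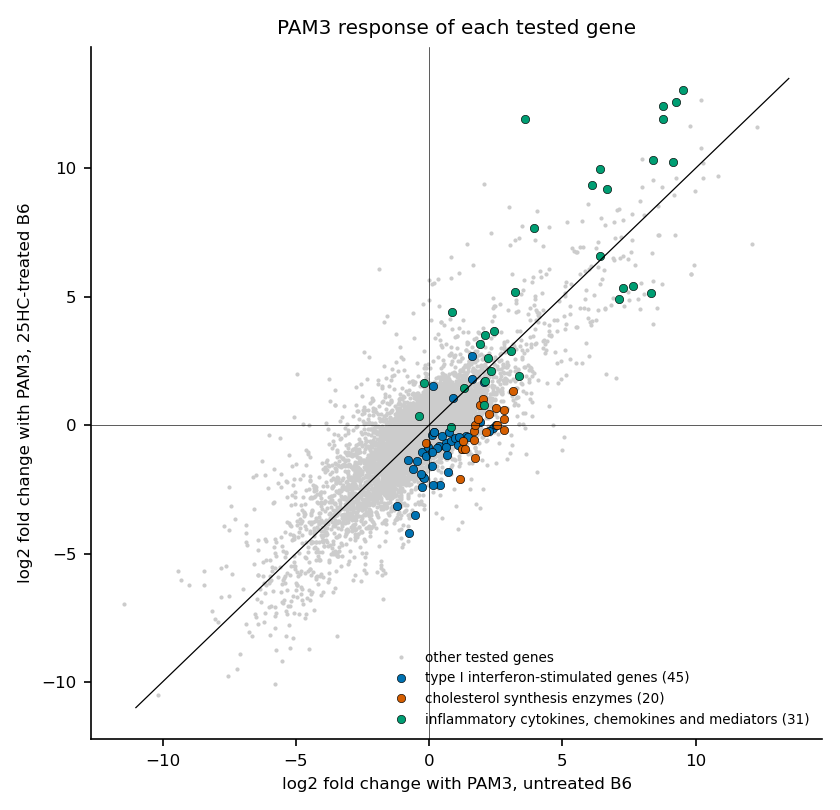
Log2 fold change of each of the 12741 tested genes with PAM3 in untreated B6 (x axis) against 25HC-treated B6 (y axis), with members of 3 lists coloured and the diagonal drawn. Cholesterol synthesis genes (medians 1.88 and -0.08) and interferon-stimulated genes (0.41 and -0.82) lie below the diagonal.

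Whether the 2 PAM3 responses differed was tested with the interaction of 25HC and PAM3 in B6. It passed for 3611 genes, 1597 above 0, where the response was higher after 25HC, and 2014 below 0. Cholesterol synthesis had 17 of 20 genes below 0 and 0 above (20 and 0 adjusted over the list alone), with a median interaction of -2.03 (camera adjusted p = 7.3e-08). Interferon-stimulated genes had 34 of 45 below 0 (35 adjusted over the list alone, median -1.51, camera adjusted p = 7.3e-08), and fatty acid synthesis 10 of 15 (median -1.19, camera adjusted p = 0.000164). These lists and the next 3 had an adjusted p = 0.682 with an estimated correlation. ATF4 genes lay below 0 in 15 of 25 and above in 1 (median -1.04, camera adjusted p = 0.00132), endoplasmic reticulum chaperones below in 11 of 20 and above in 1 (15 and 1 adjusted over the list alone, median -0.69, camera adjusted p = 0.00126), and mitochondrial respiration below in 10 of 29 (17 adjusted over the list alone, median -0.43, camera adjusted p = 0.000143). Glycolysis had 8 of 23 below 0 and 2 above (median -0.90, camera adjusted p = 0.00652, adjusted p = 0.731 with an estimated correlation).

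By gene, the interaction was -5.14 ± 0.97 for Fads2 (edgeR quasi-likelihood adjusted p = 0.00222), -5.87 ± 1.08 for Scd1, -3.25 ± 0.46 for Dhcr7 and -2.74 ± 0.45 for Mx1. It was 3.65 ± 1.04 for Il1b (edgeR adjusted p = 0.0179), 3.22 ± 0.67 for Cd86, 3.28 ± 0.34 for Cd80 and 2.79 ± 0.47 for Cd274. Cd274 rose by 3.10 with PAM3 in untreated cells and by 5.89 after 25HC, whereas Cd80 fell by 1.18 in untreated cells and rose by 2.10 after 25HC. Cd86 fell by 2.66 in untreated cells and did not pass after 25HC (0.55, edgeR adjusted p = 0.315). The largest value among genes that passed belonged to Thbs1 (7.97 ± 1.51, edgeR adjusted p = 0.00220, and 6.80 without B6 replicate 2 or 8.85 without 25HC replicate 2 at rest). Tlr6 had an interaction of 0.76 ± 0.19 (edgeR adjusted p = 0.00870) and Tlr1 of 0.13 ± 0.19 (edgeR adjusted p = 0.647). Over the 7897 genes that PAM3 changed in Ch25h-/- cells, libraries outside this test, the median interaction taken in the direction of the response was -0.35 (limma fry over n = 18 libraries, p = 0.000693), at -0.40 for rising and 0.28 for falling genes, so that the response was smaller after 25HC in both directions.

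Inflammatory mediators had a median interaction of 1.23, or 1.26 with 6 members at their bounds, with 3 of 31 above 0 and 3 below. They missed the threshold (camera adjusted p = 0.195) but passed without B6 PAM3 replicate 1 (0.0465) and with the animal as block (0.0404). The block also brought LXR targets (median -0.96, camera adjusted p = 0.195), NRF2 targets (0.39, 0.198) and cell cycle genes (-0.69, 0.309) past the threshold, at 0.0217, 0.0332 and 0.0332. The medians of the NF-kB (0.10) and antigen presentation (-0.36) lists were opposite in sign to their mean or test (camera adjusted p = 0.788 and 0.927). The count of genes was 2351 without 25HC PAM3 replicate 1 and 2288 without replicate 3.

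**Figure D5:**
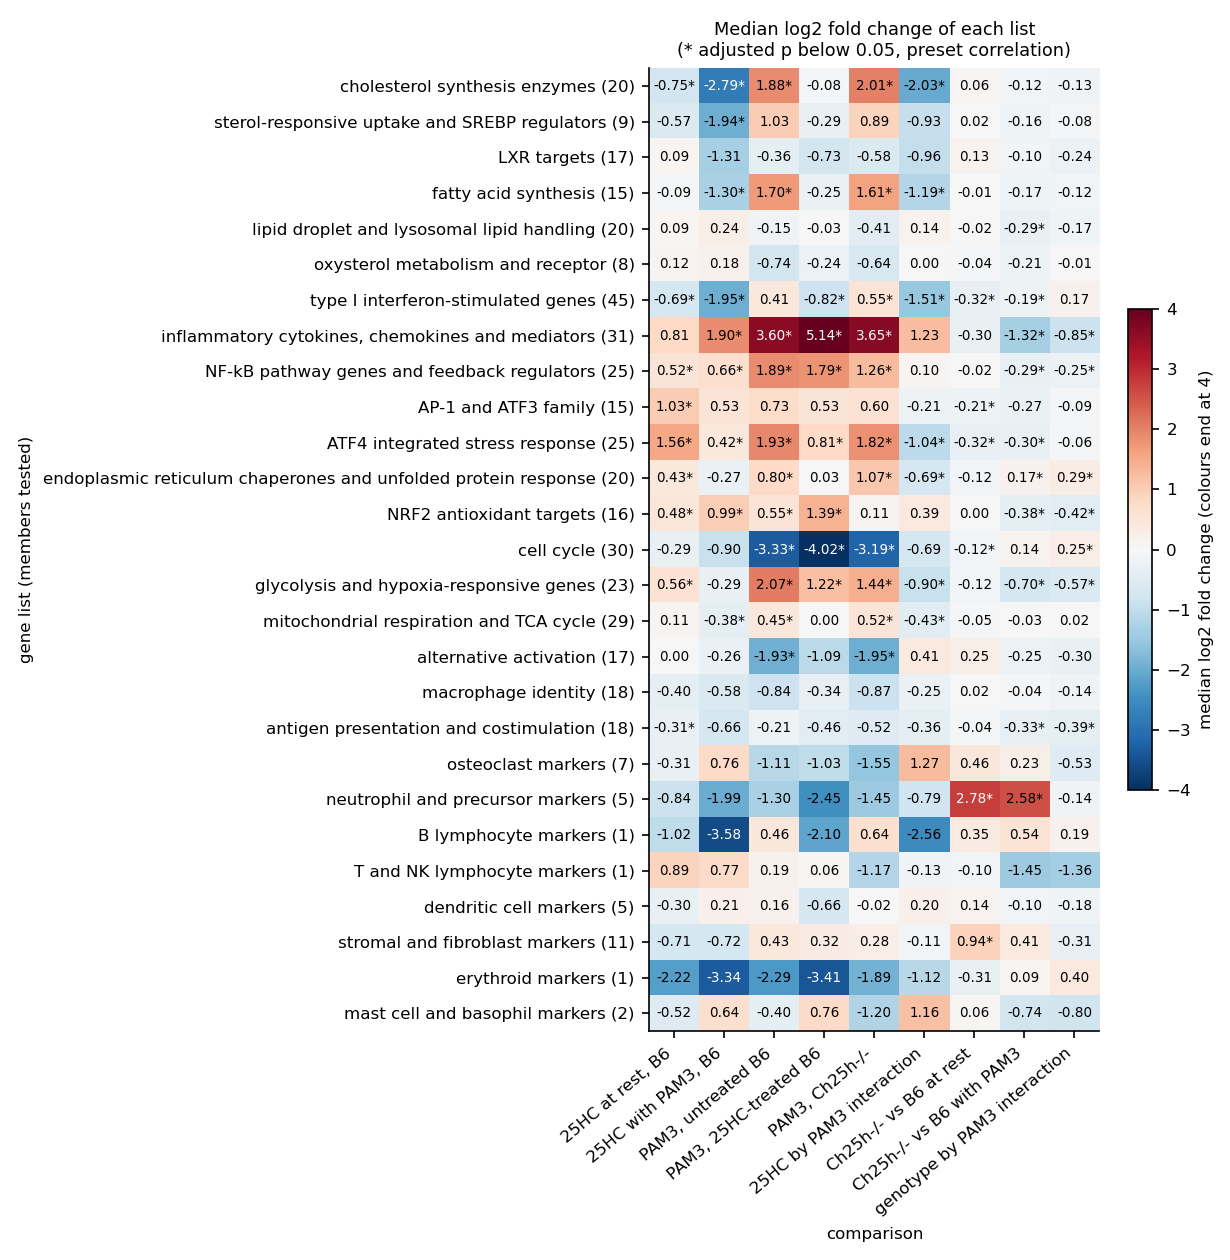
Median log2 fold change of the tested members of each of the 27 lists (vertical axis, members in brackets) in each of the 9 comparisons (horizontal axis), colour and printed value for the median and a star for a camera adjusted p below 0.05 at the preset correlation. Cholesterol synthesis lies at -0.75 and -2.79 with 25HC and at 1.88 with PAM3 in untreated B6.

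The comparison of Ch25h-/- with B6 cells at rest asked what loss of the enzyme changes before stimulation. Ch25h was the only gene that passed (-7.12 ± 0.89 SE, edgeR quasi-likelihood adjusted p = 0.00955, lower in 3 of 3 libraries). Of 12741 tested genes 704 had an unadjusted p below 0.05, little more than that threshold yields without any difference. Markers of neutrophils and their precursors were higher in Ch25h-/- cells. S100a9 (chromosome 3, 90692632 to 90695721, minus strand), a calcium-binding protein abundant in neutrophils, lay at 2.01, 1.88 and 2.20 CPM in B6 and at 4.36, 27.2 and 8.94 CPM in Ch25h-/- (2.73 ± 0.58, edgeR adjusted p = 0.328). Ltf, a neutrophil granule protein, lay at 1.11, 1.28 and 1.54 against 4.41, 19.9 and 7.33 CPM. Of the 5 tested neutrophil markers 0 passed over all genes and 5 adjusted over the list alone. Their median was 2.78 ± 0.161 (camera adjusted p = 2.7e-14, adjusted p = 0.0300 with an estimated correlation), the only list result that held under both settings. The size rested in part on Ch25h-/- replicate 2, without which the median was 1.91 (camera adjusted p = 2.8e-12). The call with an estimated correlation was lost without B6 replicate 2 (adjusted p = 0.190 with an estimated correlation).

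Other lists moved by small amounts and none of their genes passed. Interferon-stimulated genes had a median of -0.32 (camera adjusted p = 3.1e-05, adjusted p = 0.952 with an estimated correlation, and 0.0681 without B6 replicate 2) and ATF4 genes of -0.32 (camera adjusted p = 0.000915, adjusted p = 0.930 with an estimated correlation, and 0.140 without Ch25h-/- replicate 2). The AP-1 list had a median of -0.21 (camera adjusted p = 0.00368, adjusted p = 0.786 with an estimated correlation, and 0.0887 without B6 replicate 2). Cell cycle genes had a median of -0.12 (camera adjusted p = 0.0101, adjusted p = 0.952 with an estimated correlation), and missed the threshold without B6 replicate 1 (0.403) or 3 (0.609). Without replicate 2 of every group their direction turned to higher (camera adjusted p = 0.397). Stromal markers, beside the neutrophil markers, had a median of 0.94 ± 0.544 over 11 genes (camera adjusted p = 0.0129, adjusted p = 0.930 with an estimated correlation, and 0.937 without Ch25h-/- replicate 2, 0.0608 without B6 replicate 1 or 0.254 without replicate 3). Cholesterol synthesis (median 0.06, camera adjusted p = 0.911) passed without Ch25h-/- replicate 1 (0.0435) or 2 (6.3e-05). It was higher in Ch25h-/- without replicate 2 of every group (camera adjusted p = 0.0107). Ch25h-/- replicate 2 deviated by -1.24 on this list, so the direction may turn with the library left out. The synthesis gene Sqle, for instance, lay at 49.0, 6.45 and 27.0 CPM in Ch25h-/- and at 40.3, 8.53 and 28.7 CPM in B6. Without Ch25h-/- replicate 2 the uptake, fatty acid, NF-kB, NRF2 and antigen presentation lists also passed, with camera adjusted p from 0.00163 to 0.0342. Chaperones passed without B6 replicate 2 (0.00169) or Ch25h-/- replicate 1 (0.0296) or 3 (0.0171), mitochondrial respiration without Ch25h-/- replicate 1 (0.0373) and osteoclast markers without replicate 3 (0.00560). The single tested B lymphocyte (Cd79b, 0.35), T lymphocyte (Lck, -0.10) and erythroid (Epor, -0.31) markers, the 2 mast cell markers (median 0.06) and the 5 dendritic cell markers (median 0.14) did not pass.

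DESeq2 called 21 genes at rest, 11 higher and 10 lower. The edgeR count was 3 with mouse number as a block, 0 with only the compared groups in the fit, 0 without Ch25h-/- replicate 3 and 4 without replicate 1, and Ch25h missed the threshold without Ch25h-/- replicate 2 (edgeR adjusted p = 0.0744) or 3 (0.117). With the block the inflammatory and glycolysis lists also passed (camera adjusted p = 0.0453 each).

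With PAM3 the same comparison asked whether cells without Ch25h differ in the stimulated state. The inflammatory and glycolysis lists were lower in Ch25h-/- by camera at the preset correlation and not with an estimated one (adjusted p = 0.433 with an estimated correlation for both), and 0 of their genes passed over all genes. Arhgap22 (chromosome 14, 33214026 to 33369934, plus strand), a regulator of Rac signalling, fell from 13.4 ± 2.31 to 4.62 ± 1.24 CPM (-1.53 ± 0.18 SE, edgeR quasi-likelihood adjusted p = 0.00289, lower in 3 of 3 libraries). Ccr2 (chromosome 9, 124101950 to 124113557, plus strand), a chemokine receptor of monocytes, rose from 11.3 ± 1.55 to 28.4 ± 5.34 CPM (1.33 ± 0.21, edgeR adjusted p = 0.0166). Mical1, a redox regulator of actin, fell from 13.0 ± 1.23 to 4.87 ± 1.92 CPM and Sos1, a Ras exchange factor, rose from 100 ± 15.8 to 209 ± 58.3 CPM. In all, 22 genes passed, 6 higher and 16 lower, and 1784 had an unadjusted p below 0.05. Ch25h was among them (-5.64 ± 1.00, edgeR adjusted p = 0.0383). Il1b lay at 1658 ± 999.9 CPM in B6 and 363 ± 276 CPM in Ch25h-/-, short of the threshold (-2.19 ± 0.70, edgeR adjusted p = 0.158). Tlr2 lay at 361 ± 56.9 and 237 ± 29.2 CPM (edgeR adjusted p = 0.163).

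Of 31 inflammatory mediators 0 passed over all genes, and 17 were lower and 1 higher adjusted over the list alone, with a median of -1.32 ± 1.03 (camera adjusted p = 4.1e-08). Glycolysis and hypoxia genes had 15 of 23 lower adjusted over the list alone (median -0.70, camera adjusted p = 5.8e-11). Both had an adjusted p = 0.433 with an estimated correlation. The NF-kB list had 6 of 25 lower adjusted over the list alone (median -0.29, camera adjusted p = 0.000565, adjusted p = 0.528 with an estimated correlation). NRF2 targets (median -0.38, camera adjusted p = 0.000144, adjusted p = 0.435 with an estimated correlation) and ATF4 genes (median -0.30, camera adjusted p = 0.000226, adjusted p = 0.504 with an estimated correlation) were also lower. The lipid droplet list was lower (median -0.29, camera adjusted p = 0.00511, adjusted p = 0.433 with an estimated correlation, and 0.0695 without Ch25h-/- replicate 2), as was antigen presentation (median -0.33, camera adjusted p = 0.00546, adjusted p = 0.528 with an estimated correlation). Interferon-stimulated genes (median -0.19, camera adjusted p = 0.0226, adjusted p = 0.819 with an estimated correlation) missed the threshold without B6 replicate 1 (0.244) or 3 (0.214), and without replicate 2 of every group their direction turned to higher (camera adjusted p = 0.720). Endoplasmic reticulum chaperones were higher (median 0.17, camera adjusted p = 0.0111, adjusted p = 0.590 with an estimated correlation), and missed it without B6 replicate 1 (0.113) or 2 (0.0551) or Ch25h-/- replicate 2 (0.0683). Neutrophil markers were again higher (3 of 5 adjusted over the list alone, median 2.58, camera adjusted p = 0.00169, adjusted p = 0.433 with an estimated correlation).

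Genes that 25HC had changed at rest were then followed into this comparison, which shares no library with their selection. The 1886 that had risen had a median of -0.117 in Ch25h-/- with PAM3, only 26.1% of them above 0 (camera p = 5.0e-07, p = 0.305 with an estimated correlation, fry p = 0.131). The 1448 that had fallen had a median of 0.102, 36.5% of them below 0 (camera p = 2.4e-09, p = 0.155 with an estimated correlation, fry p = 0.222), a median that was 0.05003 without 25HC replicate 2 and 0.173 without B6 replicate 2 at rest. For genes changed at least 2-fold at rest the medians were -0.291 and 0.130 (camera p = 0.329 and 0.315 with an estimated correlation). Of the genes that passed in Ch25h-/- with PAM3, 5 had risen and 3 had fallen with 25HC at rest, and all 8 moved in the opposite direction here. Arhgap22, for instance, lay at 94.8 ± 13.1 CPM in B6 at rest and 147 ± 9.86 CPM after 25HC.

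Lists short of the threshold also depended on single libraries. Cholesterol synthesis passed without Ch25h-/- replicate 1 (camera adjusted p = 0.0279), 2 (0.0489) or 3 (0.00540), and fatty acid synthesis without replicate 1 (0.00519) or 3 (0.00599). Both lists ran lower in Ch25h-/- with all libraries (camera adjusted p = 0.267 and 0.138). Without replicate 2 of every group both turned to higher (0.0309 and 0.380), so their direction rests on the libraries used. The oxysterol, AP-1, cell cycle and mitochondrial lists passed without 1 or 2 of the libraries (0.0207 to 0.0447).

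The 22 genes depended on single libraries. The count was 3, 85 and 3 without B6 replicate 1, 2 and 3, and 254, 3 and 1 without Ch25h-/- replicate 1, 2 and 3, with Arhgap22 called each time. Ccr2, Sos1 and Ch25h lost their calls without B6 replicate 1 or 3 or Ch25h-/- replicate 2 or 3 (edgeR adjusted p from 0.0578 to 0.223), and Mical1 without B6 replicate 3 (0.0512) or Ch25h-/- replicate 3 (0.0578). Among the 120 tested genes within 10 Mb of Ch25h 1 passed, the renalase gene Rnls, against 20 of 12571 elsewhere (Fisher's exact test, two-sided, p = 0.181). DESeq2 called 389 genes, 135 higher and 254 lower, and edgeR 0 with only the compared groups in the fit.

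The PAM3 response of Ch25h-/- cells changed 7897 genes, 3805 higher and 4092 lower, and with library size alone the median shifted by -0.159 and the calls became 2925 higher and 4995 lower. Of the 87 named genes that passed 86 moved the same way in all 3 animals. Il10 rose from 4.02 ± 0.228 to 40.3 ± 5.57 CPM (3.33 ± 0.30 SE, edgeR quasi-likelihood adjusted p = 3.8e-07) and Tlr1 from 93.8 ± 4.16 to 539 ± 38.6 CPM. NF-kB genes rose in 20 of 25 with 1 lower (median 1.26, camera adjusted p = 6.3e-07), glycolysis in 19 of 23 with 1 lower (median 1.44, camera adjusted p = 1.7e-06), chaperones in 17 of 20 with 1 lower (median 1.07, camera adjusted p = 1.7e-06) and ATF4 genes in 21 of 25 with 1 lower (median 1.82, camera adjusted p = 1.3e-05). These 4 lists had an adjusted p = 0.607 with an estimated correlation. Cholesterol synthesis rose in 19 of 20 (median 2.01, camera adjusted p = 1.8e-05) and inflammatory mediators in 20 of 31 with 2 lower (median 3.65, or 2.72 with 8 members at their bounds, camera adjusted p = 0.000641). Mitochondrial respiration rose in 20 of 29 with 2 lower (median 0.52, camera adjusted p = 2.7e-05), fatty acid synthesis in 11 of 15 with 1 lower (median 1.61, camera adjusted p = 0.0119), and cell cycle genes fell in 26 of 30 (median -3.19, camera adjusted p = 2.1e-05). These 5 had an adjusted p = 0.614 with an estimated correlation. Alternative activation fell in 12 of 17 with 2 higher (median -1.95, camera adjusted p = 0.00786, adjusted p = 0.191 with an estimated correlation). Interferon-stimulated genes rose in 19 of 45 (18 adjusted over the list alone, median 0.55, camera adjusted p = 0.0366, adjusted p = 0.734 with an estimated correlation), but not past the threshold without Ch25h-/- PAM3 replicate 1 (0.323) or 3 (0.154).

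The interaction of genotype and PAM3 tested whether these responses differed. With edgeR 0 genes passed (lowest adjusted p = 0.481), and DESeq2 called 2. Of 12741 tested genes 598 had an unadjusted edgeR p below 0.05, fewer than that threshold yields without any difference. As lists, glycolysis (median -0.57, camera adjusted p = 5.9e-09) and NRF2 targets (median -0.42, camera adjusted p = 3.5e-07) responded less in Ch25h-/-, both with adjusted p = 0.586 with an estimated correlation. Chaperones responded more (median 0.29, camera adjusted p = 7.7e-05, adjusted p = 0.649 with an estimated correlation). Inflammatory mediators (median -0.85, or -1.16 with 8 members at their bounds, camera adjusted p = 0.00102) and NF-kB genes (median -0.25, camera adjusted p = 0.00403) responded less, both with adjusted p = 0.790 with an estimated correlation. The inflammatory list missed the threshold without B6 replicate 2 at rest (0.0799), and the NF-kB list without Ch25h-/- replicate 2 at rest (0.377). Antigen presentation (median -0.39, camera adjusted p = 0.00751, adjusted p = 0.789 with an estimated correlation) missed it without replicate 3 of B6 at rest (0.109) or with PAM3 (0.0698), or replicate 2 of Ch25h-/- at rest (0.571) or with PAM3 (0.0657). Cell cycle genes (median 0.25, camera adjusted p = 0.0147, adjusted p = 0.869 with an estimated correlation) missed it without B6 replicate 1 (0.158) or 3 (0.163) at rest, B6 PAM3 replicate 2 (0.161) or Ch25h-/- PAM3 replicate 1 (0.156) or 3 (0.148). Over the 7507 genes that PAM3 changed in 25HC-treated cells the median interaction in the direction of the response was -0.029 (limma fry over n = 18 libraries, p = 0.537), and it lay at 0.0122 without B6 replicate 2 at rest and 0.0209 without B6 PAM3 replicate 1. Interferon-stimulated genes (median 0.17, camera adjusted p = 0.421) passed without Ch25h-/- PAM3 replicate 2 (1.4e-16) or B6 replicate 3 at rest (0.0351). Cholesterol synthesis (median -0.13, camera adjusted p = 0.264) passed when any 1 of 4 libraries was left out (7.4e-06 to 0.0340), as did fatty acid synthesis (0.000600 to 0.0271) and lipid droplets (0.00303 to 0.0377). Stromal markers passed without 2 libraries (0.00643 and 0.0130), and the uptake (0.0223), LXR (0.0472) and mitochondrial (0.00403) lists without 1.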

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

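The tests of depth and scaling below were chosen after the number of genes was seen. Each value here stood out because the interaction test found that the PAM3 response differed between 25HC-treated and untreated cells, so that it cannot be read from either group alone.

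With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, the interaction passed for 3611 genes, 1597 above 0 and 2014 below. Of the lists, the median interaction was -2.03 for cholesterol synthesis, -1.19 for fatty acid synthesis, -1.51 for interferon-stimulated genes, -1.04 for ATF4 genes, -0.69 for endoplasmic reticulum chaperones, -0.90 for glycolysis and -0.43 for mitochondrial respiration. Over the genes of the PAM3 response the signed median was -0.35.

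The named genes with the lowest interactions included 2 desaturase genes, Scd1 at -5.87 and Fads2 at -5.14. Nox1, a subunit of an NADPH oxidase, lay at -5.13 and went from 9.29 ± 0.486 to 1.15 ± 0.221 CPM with PAM3 when 25HC was present. Olfml3, a secreted matrix protein, lay at -4.84 (-5.65 without 25HC PAM3 replicate 2), Cd244, an immune receptor, at -3.98, BC147527 at -3.91 and Gpr84, a fatty acid receptor, at -3.52 (-2.87 without 25HC replicate 1 at rest). Among the highest were Thbs1 at 7.97, the signalling inhibitor gene Socs2 at 5.80 (7.29 without B6 PAM3 replicate 1 and 4.99 without replicate 2), the platelet chemokine gene Ppbp at 5.62, the RNA-binding protein gene Samd4 at 5.61, Ahr, which encodes a ligand-activated transcription factor, at 5.39 (6.38 without B6 PAM3 replicate 1), the transcription factor gene Sox4 at 5.37, the collagenase gene Mmp8 at 5.35 and the lectin receptor gene Clec4n at 4.98 (5.66 without B6 PAM3 replicate 1).

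Unequal depth and scaling were weighed as causes of the count of 3611 genes. After every library was thinned to the same total 3083 genes passed, which argues against depth as the whole cause. The lower of the counts with other scaling was 3552, which argues against the scaling factors. Of 100 splits of the same libraries 3 reached as many genes, the real one and others up to 4708, and among the 13 splits that part as many pairs the highest other was 2695. Both splits above the real count left the PAM3 libraries as they were and regrouped those at rest. All other splits of that kind called 1533 to 4708 genes, whereas splits that regrouped the PAM3 libraries called 0, apart from a split with 1541. Leaving the PAM3 libraries as they were keeps the 25HC difference with PAM3, which by itself called 5750 genes. These splits therefore cannot tell how many genes an absent interaction would give.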

How the results depend on the processing

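Scaling by library size alone, thinning, removal of replicate 2 from every group and the estimated correlation with a block were tests chosen after seeing the data. Unless stated, the cause was not tested.

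For 25HC at rest 3334 genes became 5103 without replicate 2 in every group and 1524 to 3801 with 1 library left out. With PAM3 the 25HC count of 5750 ranged from 4484 to 6096, and the PAM3 responses from 7298 to 7753 in untreated B6, 6498 to 7073 after 25HC and 7001 to 7667 in Ch25h-/-. The 25HC interaction of 3611 genes ranged from 2288 to 4481. For Ch25h-/- against B6 at rest the count of 1 became 0 without genes near Ch25h, by construction as Ch25h itself is removed, 0 with only the groups compared, 21 with DESeq2, 2 without replicate 2 and 0 to 4 with 1 library left out. With PAM3 the count of 22 became 14 with library size alone, 13 without a filter, 0 with only the groups compared, 389 with DESeq2, 10 after thinning, 384 without replicate 2 and 1 to 254 with 1 library left out. The genotype interaction had 2 with DESeq2 and 0 with any library left out.

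With the mouse number as block the genotype counts were 3 at rest and 141 with PAM3, where the pairing was not clear. The block gave 4196 genes for 25HC at rest, 6374 with PAM3 and 4513 for the interaction, and changed no list call other than those named beside the results and, for genotype with PAM3, the oxysterol and AP-1 lists (adjusted p = 0.0286 each by limma camera).

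Of 77 list results past the threshold, 1 remained with an estimated correlation and 1 with that and a block, while fry called 92. The 1 that remained, neutrophil markers in Ch25h-/- at rest, had a camera adjusted p = 0.190 with an estimated correlation without B6 replicate 2, a test also chosen after seeing the data. Leaving out 1 library gave 75 to 84. Without replicate 2 of every group list calls were both gained and lost. In Ch25h-/- against B6, for example, cell cycle genes were then higher with PAM3 (camera adjusted p = 0.000952). At rest NRF2 targets were higher (0.0148) and glycolysis genes lower (0.0338), while the call of stromal markers was lost (0.142). With an estimated correlation the sets of genes changed by 25HC at rest kept their medians but not their calls, with camera p = 0.305 (-0.117) and 0.155 (0.102) in Ch25h-/- with PAM3 and 0.140 (0.271) and 0.160 (-0.424) in 25HC with PAM3. With 1 library left out those medians ranged from -0.165 to -0.0809, 0.05003 to 0.173, 0.228 to 0.380 and -0.553 to -0.308.

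The PAM3 response size after 25HC ranged from -0.416 to -0.283. In Ch25h-/- it ranged from -0.0676 to 0.0209 and was reversed, at 0.0122 and 0.0209, without B6 replicate 2 at rest or B6 PAM3 replicate 1. Over 772 pairs of named gene and comparison, 12781 values gave 0 reversals and 313 calls lost.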

Other observations

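The second neutrophil list, the stromal comparison and the tests of replicate 2 below were tests chosen after the patterns had been seen.

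Genes that sense or handle sterols fell with PAM3 whatever the treatment. Gpr183, the receptor for dihydroxylated oxysterols, fell from 38.5 ± 5.38 to 3.30 ± 0.526 CPM in untreated B6 (log2 fold change -3.56, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), by 3.81 after 25HC and from 43.9 ± 12.5 to 1.80 ± 0.811 CPM in Ch25h-/-. Lipa, the lysosomal acid lipase, fell from 1673 ± 235 to 443 ± 43.2 CPM in untreated B6, and by 1.78 and 1.74 on the log2 scale in the other settings.

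Neutrophil markers were higher in Ch25h-/- cells at rest, with a median of 2.78 ± 0.161, or 1.91 without Ch25h-/- replicate 2, which deviated by 1.78 on this list. Residual cells of that lineage may account for this, but a second marker list had a median of 0.059, which by the plan of that test would count against it. That list was then set aside because only 6 of its 16 members were tested, under a rule of at least 0.5 of members that was added after the result was seen, so the test cannot tell. The summed CPM of the 9 untested members found in the count table, looked at afterwards, was 0.216, 0.446 and 0.415 in B6 and 0.693, 4.04 and 1.25 in Ch25h-/-. After thinning the first list had a median of 2.84, against depth as a cause, and stromal markers had 0.94 ± 0.544, against a uniformly lower share of macrophages.

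Replicate 2 at rest stood apart in both genotypes, with deviations that correlated across genes at r = 0.705 (genes are not independent replicates). After thinning r was 0.690, against depth, and GC content and transcript length explained at most 13.4% of the variance across genes, against those. Cholesterol synthesis genes deviated by -0.84 in B6 and -1.24 in Ch25h-/-, and Abca1, a cholesterol exporter, lay at 1574 CPM in B6 replicate 2 (642 and 994 in the others), which could reflect a sterol-rich state of these cultures. Genes that 25HC lowered at least 2-fold with PAM3 deviated by 0.200 and 0, which does not follow from such a state, so the test cannot tell. Cell cycle genes deviated by -1.27 and -2.74, a sign that growth of the cultures might also have differed.

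For comparisons of 2 groups only 10 splits exist, too few for a share under 0.05. The real split alone (1) reached its count for 25HC at rest (3334, highest other 0), 25HC with PAM3 (5750, 0), PAM3 in untreated B6 (7912, 17), PAM3 after 25HC (7507, 0), PAM3 in Ch25h-/- (7897, 0) and Ch25h-/- against B6 with PAM3 (22, 0). For genotype at rest 2 splits reached the real count of 1, and the other one, which set replicate 2 of both genotypes and Ch25h-/- replicate 3 against the rest, called 768 genes and points to the structure of the samples that replicate 2 forms. For the genotype interaction the real count is 0, which all 100 splits reach whatever the data (up to 144 in others), so these splits cannot tell.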
